A study of Homo sapiens with 6 samples.

How the data were processed

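Polyadenylation selection or depletion, the aligner, the read counter and the annotation release are not given in the sources used here. Total RNA was made into libraries with a directional kit, per the labels' protocols, and the genome build was hg38, per the submitters' processing notes. Whether reads were counted by strand is not given, so reads of a gene and of an overlapping antisense gene could be mixed. The authors deposited 1 table of FPKM values (fragments per kilobase of gene length, scaled to library size) for 58735 genes, 1 column per library, with a length in bases listed for each gene. Each column was assigned to its library by its title, and groups and replicate numbers come from the library titles.

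The scaling of the FPKM values was worked out from the values themselves. In every library, FPKM times the deposited gene length was a whole number of reads times 1 factor, within a tolerance of 0.01 reads for 100% of the values above 0. The factor equalled that of a median-of-ratios size factor, computed over the 18279 genes with reads in all libraries, times the geometric mean of the library totals. So the libraries had been scaled to each other before deposit. The recovered reads came to 89881373 over the 6 libraries, 14087260 to 15724750 each, and 27543 genes were at 0 in all of them. At this depth 1 read is a small fraction of 1 FPKM for genes of usual length, so for them the filter stands above the counting floor. For the shortest 1359 genes tested (42 to 505 bases) 1 FPKM is only a few reads or fewer, so for them it does not. Of the gene identifiers, 58207 matched a current symbol, and 58690 have the same coordinates in GENCODE 29, from which GC content was taken; names in the table are older (CYR61 for CCN1, CTGF for CCN2).

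Libraries of the same group were compared before averaging. The chi-square of their recovered reads per degree of freedom ran from 2.475 (DMSO replicates 1 and 2) to 98.73 (inhibitor replicates 2 and 3), so no pair differed by sampling noise alone and each library counted as 1 replicate.

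Genes at 1 FPKM or more in at least 3 of the 6 libraries, whichever group, were tested (13578 genes). Values were log2(FPKM + 1), fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, no block), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 33 gene lists (699 genes found in the table) were fixed before the data were examined and compared with the remaining genes by camera from limma with a preset inter-gene correlation of 0.01, adjusted over the 31 lists with measured members; camera with an estimated correlation and fry were run beside it. Adjusted p-values of lists are camera's, those of genes are limma's. The planned main test assumed FPKM, and the file held FPKM, so it was used as written; the tests planned for counts were not run, and limma-voom on recovered reads took their place. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the plots.

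The genes named were set by a rule fixed before the data were examined: PRMT5, WDR77, STK3, STK4, LATS1, LATS2, YAP1, WWTR1, CCN1, CCN2, ANKRD1, AMOTL2, AXL, MTAP and CDKN2A always; the 12 largest rises and 12 largest falls among called genes with an official symbol whose 3 libraries of one group all lay above the 3 of the other, which chance alone gives for 10% of genes; and from each list up to 4 called members with the smallest adjusted p or, where none was called, the 2 with the highest mean FPKM. Genes named outside this rule are said to be so where they appear.

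The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, TPM, median-ratio and quantile scaling, rescaling without mitochondrial and the 50 most abundant genes, limma without a trend or with a robust prior, a replicate block, leaving out each library in turn, removal of a smooth trend on gene length and GC content (loess, span 0.3), stricter thresholds, protein-coding genes only, and the other list tests. Estimated library weights, limma-voom on the recovered reads, and leaving out inhibitor replicate 2 with the trend removed were added after seeing the data.

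The test was tried on simulated reads for the same 13578 genes, with 200 of them changed. With replicates alike, it recovered 46.3% of 1.5-fold, 77.6% of 2-fold and 89.4% of 4-fold changes, with 6 false calls of 148. With inhibitor replicate 2 given its observed deviation, it recovered 0%, 23.9% and 75.8%, with 2 false calls of 68. In the data 2339 genes were called, far more than the 200 changed here, so the adjusted threshold is less strict there. These shares and false calls therefore do not carry over directly to the data. Of 31 simulated lists the 1 that was shifted was called (adjusted p = 4.2e-66) and 0 of the 30 unchanged lists were. In the real data 12 lists were called with the preset correlation and 0 with an estimated one. The simulated lists therefore do not show how often list calls are false there.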

Results

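RNA sequencing was analysed in 6 libraries labelled BxPC-3, an established human cell line derived from a pancreatic adenocarcinoma. In 3 libraries the cells had received DMSO, and in the other 3 GSK3326595, a small-molecule inhibitor of PRMT5, the enzyme that places symmetric dimethyl marks on arginine residues. Dose and duration are not given in the sources used here. The title of the series concerns MST2, the Hippo pathway kinase encoded by STK3, as a substrate of PRMT5, so the comparison asks which transcripts, and in particular which genes read as Hippo pathway output, differed when PRMT5 was inhibited. The design text of the series speaks of a knockdown, whereas the label of each library names the inhibitor; the library labels were followed. The deposited values are FPKM, from which whole reads could be recovered: the DMSO libraries held 15302555, 14201282 and 14858308 reads and the inhibitor libraries 15724750, 14087260 and 15707218. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

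Inhibitor replicate 2 stood apart from the other 2 inhibitor libraries. Across the 13578 genes tested, which are not independent replicates, its log2 values correlated with those of inhibitor replicates 1 and 3 at r = 0.906 and r = 0.904, whereas replicates 1 and 3 correlated at r = 0.980 and the DMSO libraries with each other at r = 0.980 to 0.983. Mitochondrially encoded transcripts took 11.3% of its reads, against 6.03% and 5.84% in inhibitor replicates 1 and 3 and 4.703% to 5.01% in DMSO. Among reads from nuclear protein-coding genes, those with a listed length under 1.5 kilobases took 1.09% in this library, against 2.27% to 2.61% in the other 5 libraries. Every count of list members below is therefore also given without this library, a choice made after seeing the data.

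**Figure D1:**
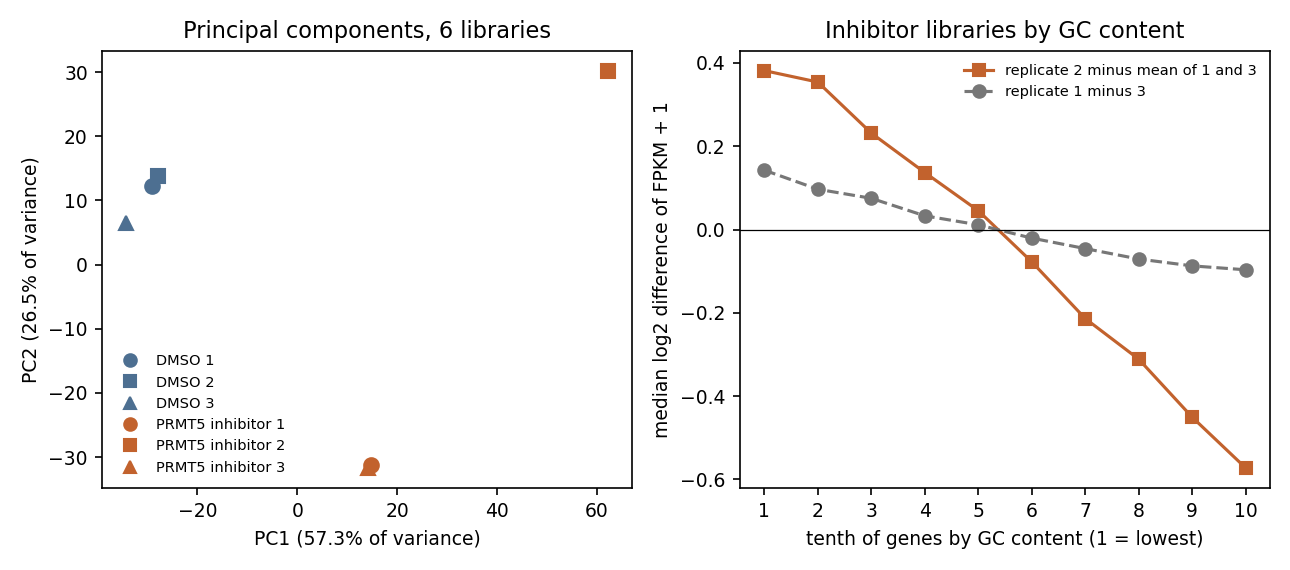
Left, the first and second principal components of the log2(FPKM + 1) values, with one point per library. Right, the median log2 difference between inhibitor libraries in groups of genes of increasing GC content: replicate 2 minus the mean of replicates 1 and 3 (squares) ran from 0.38 in the lowest group to −0.57 in the highest, and replicate 1 minus replicate 3 (circles) from 0.14 to −0.10.

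Some genes bear on the identity of the cells, and were chosen after their values were seen. KRT19, CEACAM6, ESRP1 and PDX1 had 0 reads in all 6 libraries; 3 reads over the 6 libraries, the limit that a count of 0 allows, correspond to 0.0141 FPKM for KRT19, 0.0108 for CEACAM6, 0.00675 for ESRP1 and 0.0132 for PDX1, a limit that covers counting error only. In the DMSO libraries (SD, n = 3) CDH1, which encodes E-cadherin, stood at 0.118 ± 0.0273 FPKM and EPCAM at 0.211 ± 0.0945 FPKM, while the keratins of simple epithelia KRT8 and KRT18, whose coordinates overlap, and KRT7 stood at 264 ± 16.1, 255 ± 11.5 and 163 ± 12.4, VIM at 62.8 ± 4.202, CDKN2A at 107 ± 11.2, SMAD4 at 3.64 ± 0.283 and MTAP at 2.42 ± 0.208 FPKM.

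PRMT5 itself (ENSG00000100462, chromosome 14, 22920511 to 22929585, hg38) was lower in all 3 inhibitor libraries. It stood at 23.2, 24.6 and 26.2 FPKM in DMSO and at 13.4, 12.8 and 12.1 FPKM with the inhibitor, a log2 fold change of −0.90 (SE 0.11, adjusted p = 0.00493). WDR77, its partner in the methylosome, fell by 0.48 on the log2 scale from 17.1 ± 0.602 to 11.98 ± 1.47 FPKM (SD, n = 3 each; adjusted p = 0.0397), and PRMT1, the main source of asymmetric dimethylation, fell by 0.84 (adjusted p = 0.0356). PRMT5 and PRMT1 were the only members called among the 8 measured arginine methyltransferases. Of the arginine methyltransferases, 2 fell and 0 rose when adjusted over the list alone, and 2 fell and 1 rose without inhibitor replicate 2. The arginine methyltransferases as a list had a median of −0.08, and −0.11 without inhibitor replicate 2 (camera, adjusted p = 0.474, or adjusted p = 0.693 with an estimated correlation). PRMT5 was called without each library in turn, whereas the calls of PRMT1 and WDR77 were lost without at least 1 library (highest adjusted p of each, 0.132 to 0.155). PRMT1 and WDR77 were each called in only 2 of the 6 fits that left out 1 library. The call of WDR77 was also lost with quantile normalization and when length and GC trends were removed.

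Of 13578 genes tested, 2339 differed between inhibitor and DMSO at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 975 higher and 1364 lower with the inhibitor. Among these, 292 rose and 395 fell by at least 1 on the log2 scale, and 1864 of the called genes were protein-coding. The excess of falls depended on the setting: with quantile normalization 1037 were higher and 1053 lower, and with length and GC trends removed 1963 and 2098. At 1 or more on the log2 scale the balance turned in some settings, with 544 higher and 503 lower at a pseudocount of 0.1, 426 and 343 with trends removed, and 413 and 373 without inhibitor replicate 2. With limma-voom on recovered reads, added after seeing the data, they were 584 and 572. At an unadjusted p under 0.05 there were 4697, and the median log2 fold change of all genes tested was −0.05. No called gene changed sign when 1 library was left out, but the count depended on which libraries were included. Without inhibitor replicate 2 it was 5513 (2372 higher and 3141 lower), including 2334 of the 2339 with the same sign, whereas it was 478, 510 and 579 without DMSO replicates 1, 2 and 3 and 1091 and 1299 without inhibitor replicates 1 and 3.

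To ask whether Hippo pathway output differed, the transcripts of YAP and TAZ target genes were compared. Several of these targets were lower with the inhibitor. CCN1 (listed as CYR61; ENSG00000142871, chromosome 1, 85580761 to 85583962), a matricellular protein, went from 195 ± 3.38 FPKM in DMSO to 35.4 ± 11.99 FPKM (SD, n = 3 each), a log2 fold change of −2.49 (SE 0.27, adjusted p = 0.00388; −2.18 without inhibitor replicate 2). CCN2 (listed as CTGF; ENSG00000118523, chromosome 6, 131948176 to 131951373) went from 20.6 ± 0.779 to 5.66 ± 0.635 FPKM (log2 fold change −1.70, SE 0.11, adjusted p = 0.00115), and ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276) from 4.05 ± 0.349 to 0.450 ± 0.311 FPKM (log2 fold change −1.82, SE 0.18, adjusted p = 0.00325). NT5E, a cell-surface nucleotidase, fell by 2.11 and AMOTL2, a feedback regulator of YAP, by 0.60 on the log2 scale. In all, 7 of the 21 measured targets fell and 1 rose; NUAK2 (−0.77), GADD45A (−1.62) and the riser CCDC80 (0.63) complete that count and were named after their values were seen. For the YAP and TAZ targets the counts were 9 lower and 1 higher adjusted over the list alone, and 10 lower and 4 higher without inhibitor replicate 2. AXL stood at 40.2 ± 2.73 FPKM in DMSO and 27.9 ± 8.36 FPKM with the inhibitor and was not called (log2 fold change −0.55, adjusted p = 0.119), although it was without inhibitor replicate 2 (−0.77). The median of the list was −0.32, and as a whole the list did not pass the test against other genes (camera, adjusted p = 0.0635; adjusted p = 0.343 with an estimated correlation). It passed without inhibitor replicate 2 (adjusted p = 0.0383, but adjusted p = 0.469 with an estimated correlation), where its median was −0.14.

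With all libraries no call was made for the kinases and co-activators of the pathway. STK3 (ENSG00000104375, chromosome 8, 98371228 to 98942827) stood at 2.65 ± 0.227 FPKM in DMSO and 2.45 ± 0.831 FPKM with the inhibitor (log2 fold change −0.11, SE 0.19, adjusted p = 0.717). It was called lower when length and GC trends were removed (−0.28, SE 0.08, adjusted p = 0.0489). The log2 fold changes were −0.07 for STK4, −0.07 for LATS1, 0.16 for LATS2, −0.10 for YAP1 and 0.24 for WWTR1, which encodes TAZ, each with a standard error of 0.12 to 0.18. The signs of the small values depended on the setting: STK4 and YAP1 were above 0 with quantile normalization, LATS1 without inhibitor replicate 1 or 3 and STK3 without inhibitor replicate 3. Of the 24 measured pathway components, 3 fell: the upstream scaffolds FRMD6 (−0.71) and WWC1 (−0.56) and the transcription factor TEAD4 (−0.68). Without inhibitor replicate 2, 6 of the pathway components fell and 2 rose, and adjusted over the list alone 3 fell and 0 rose. The pathway components as a list had a median of −0.07, and −0.13 without inhibitor replicate 2 (camera, adjusted p = 0.877, or adjusted p = 0.943 with an estimated correlation). Of the genes named for YAP and TAZ targets and the pathway, AMOTL2, NUAK2, GADD45A, CCDC80, FRMD6, WWC1 and TEAD4 lost their calls without at least 1 library (highest adjusted p of each, 0.0711 to 0.118). Each was called in only 1 to 3 of the 6 fits that left out 1 library.

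**Figure D2:**
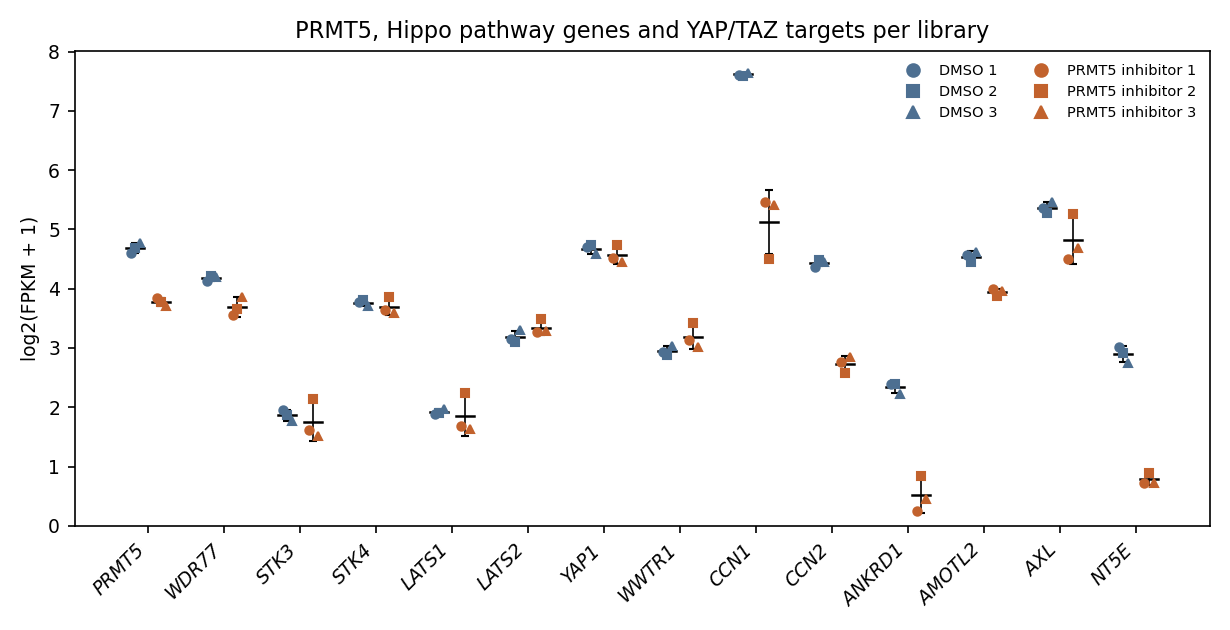
Values of PRMT5, WDR77, Hippo pathway genes and YAP and TAZ targets on the log2(FPKM + 1) scale, with one point per library (DMSO blue, inhibitor orange, shape by replicate number), the mean as a bar and the SD of 3 libraries as whiskers. CCN1, CCN2, ANKRD1 and NT5E lie lower in all 3 inhibitor libraries, while the values of STK3, STK4 and YAP1 overlap between groups.

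The genes with the largest falls included stress-responsive, keratin and cytokine genes. MT2A, a metallothionein that binds zinc and copper, went from 740.3 ± 94.5 to 64.2 ± 32.4 FPKM (SD, n = 3 each; log2 fold change −3.66, SE 0.43, adjusted p = 0.00509). KRT34, a hair keratin (ENSG00000131737, chromosome 17, 41377650 to 41382403), went from 14.8 ± 1.39 to 0.541 ± 0.0638 FPKM (−3.36), the stress-induced cytokine GDF15 from 164 ± 13.6 to 18.9 ± 9.98 (−3.22) and the inflammatory cytokine IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) from 11.8 ± 1.102 to 0.547 ± 0.259 (−3.06). The others of the 12 largest falls were MT4 (−3.07), the small GTPase GEM (−2.67), the MAPK phosphatase DUSP5 (−2.62), MYEOV (−2.53), the lysosomal protease CTSL (−2.52), CCN1, the protease inhibitor SERPINE2 (−2.48) and the prostaglandin E synthase PTGES (−2.41). Metallothionein genes are close copies of one another, so how reads were divided among MT2A, MT4 and their relatives is uncertain. All 12 were called without each library in turn.

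On the log2(FPKM + 1) scale the largest rise was that of USH1C, the scaffold protein harmonin (ENSG00000006611, chromosome 11, 17493895 to 17544416), from 0.889 ± 0.280 to 14.2 ± 1.602 FPKM (SD, n = 3 each; log2 fold change 3.01, SE 0.15, adjusted p = 0.000662). ALPI, listed as intestinal alkaline phosphatase, went from 97.01 ± 10.9 to 579 ± 166 FPKM (2.52), though its near-identical relatives ALPP and ALPG make the assignment of its reads uncertain. The imprinted, retrotransposon-derived gene PEG10 (2.22), the protease inhibitor PZP (2.20), the monoamine transporter SLC29A4 (2.19), the long noncoding RNA PURPL (2.11) and the extracellular matrix gene OLFML2A (2.06) followed. S100A5 (2.05), whose ratio of means was the largest of the 12 (20.1 against 15.9 for USH1C), INSL4 (2.02), the epithelial protease inhibitor SPINK5 (1.99), the transcription factor FOXN1 (1.96) and the granule protease GZMM (1.94) completed the 12. S100A5, listed at 784 bases, stood at 0.199 ± 0.0521 FPKM in DMSO. That is only a few reads per library, so the size of its ratio is uncertain. Of the 12 largest rises, GZMM alone lost its call when a library was left out (highest adjusted p = 0.0982). It was called in 1 of the 6 fits that left out 1 library.

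**Figure D3:**
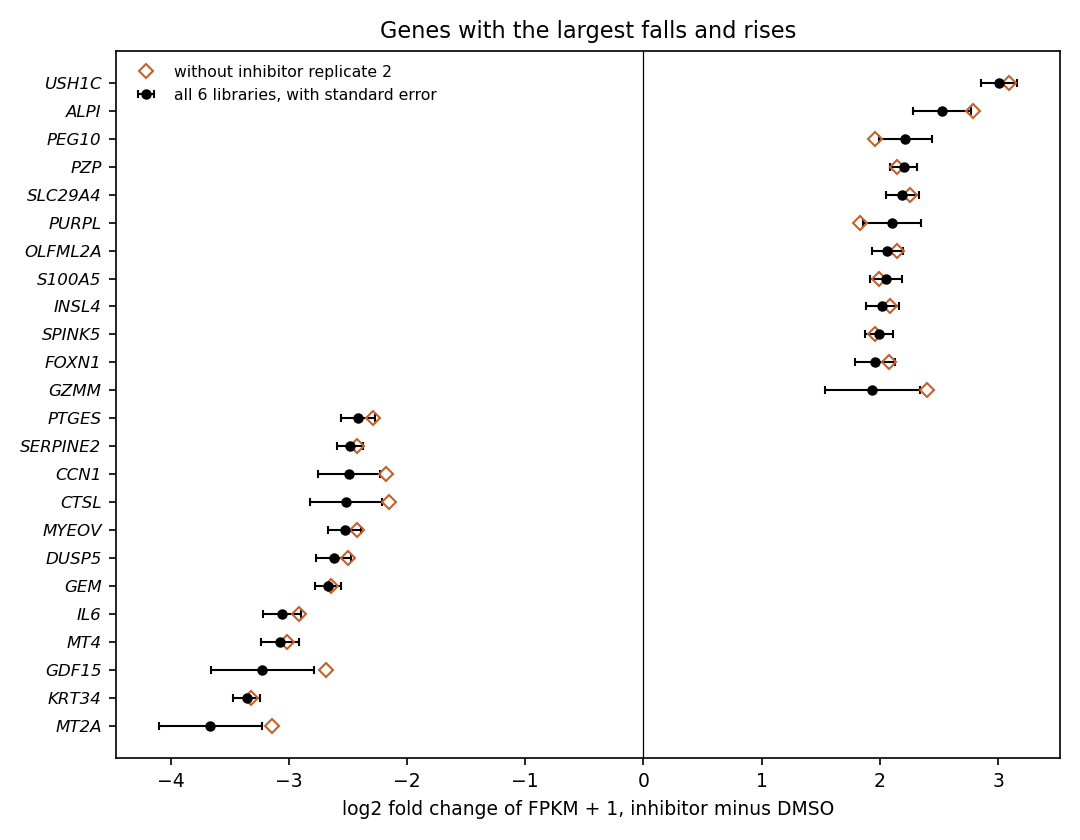
The 12 called genes with the largest falls and the 12 with the largest rises (log2 fold change of FPKM + 1, inhibitor minus DMSO; filled points with standard error for all 6 libraries, open diamonds without inhibitor replicate 2). The falls reach −3.66 for MT2A and the rises 3.01 for USH1C, and each gene keeps its sign without inhibitor replicate 2.

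NF-κB targets and cytokines fell nearly throughout. Of 13 measured members, 12 fell and none rose, among them IL6, the NF-κB inhibitor TNFAIP3 (22.9 to 4.42 FPKM, −2.14), the adhesion molecule ICAM1 (40.8 to 7.64 FPKM, −2.27) and the NF-κB subunit RELB (−2.19). Of the NF-κB targets and cytokines, 13 fell and 0 rose when adjusted over the list alone, and 13 fell and 0 rose without inhibitor replicate 2. The list median was −1.61 (camera, adjusted p = 6.3e-11; adjusted p = 0.144 with an estimated correlation). Genes that report MAPK pathway output fell as well, 11 of 14: PHLDA1 went from 13.6 to 1.86 FPKM (−2.35), DUSP5 from 109 ± 8.23 to 16.96 ± 2.75 FPKM (−2.62), DUSP4 changed by −2.08 and the AP-1 subunit FOSL1 by −2.02. For the MAPK output genes the counts were 12 lower and 0 higher adjusted over the list alone, and 13 lower and 0 higher without inhibitor replicate 2. Their median was −1.38 (adjusted p = 2.0e-09; adjusted p = 0.144 with an estimated correlation). Of 14 immediate early and heat shock genes 8 fell, with a median of −1.21 (adjusted p = 2.2e-06; adjusted p = 0.199 with an estimated correlation). Adjusted over the list alone, 10 of the immediate early and heat shock genes fell and 0 rose; without inhibitor replicate 2 it was 11 and 0. JUN went from 30.04 to 5.87 FPKM (−2.18), FOSB changed by −1.55, the co-chaperone DNAJB1 by −1.26 and HSPA1B, which is nearly identical to HSPA1A, by −1.62. The genes named from these 3 lists were called without each library in turn.

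In the lists of RNA processing and ribosome biogenesis a minority of members were called, all of them lower. Of 28 splicing regulators 8 fell and none rose, including SRSF3 (30.6 to 19.97 FPKM, −0.59), SRSF7 (−0.66), RBM39 (−0.61) and TRA2B (−0.63); the median was −0.44 (camera, adjusted p = 0.000117; adjusted p = 0.375 with an estimated correlation). Of the splicing regulators, 12 fell and 0 rose when adjusted over the list alone, and 20 fell and 0 rose without inhibitor replicate 2. The Sm and small nuclear ribonucleoprotein genes, only some of which encode substrates of PRMT5, had 2 falls among 18, SNRPF (−0.73) and SNRPG (−0.74). For the Sm and small nuclear ribonucleoprotein genes the counts were 0 lower and 0 higher adjusted over the list alone, and 8 lower and 1 higher without inhibitor replicate 2. The Sm and small nuclear ribonucleoprotein genes as a list had a median of −0.43, and −0.28 without inhibitor replicate 2 (camera, adjusted p = 0.0127, or adjusted p = 0.451 with an estimated correlation). Their list was not called with the filter at 5 FPKM (adjusted p = 0.0741). Ribosome biogenesis and MYC-linked genes showed 6 falls among 29, such as RRP9 (−1.20), BYSL (−0.80), NIP7 (−0.60) and PES1 (−0.53), and no rise. Without inhibitor replicate 2, 18 of the ribosome biogenesis genes fell and 0 rose, and adjusted over the list alone 7 fell and 0 rose. The ribosome biogenesis genes as a list had a median of −0.37, and −0.35 without inhibitor replicate 2 (camera, adjusted p = 0.00114, or adjusted p = 0.144 with an estimated correlation). Of 16 genes of the endoplasmic reticulum unfolded protein response 7 fell, among them the chaperones HSPA5 (387 to 237 FPKM, −0.71) and CALR (−0.70), EDEM1 (−0.68) and DNAJB11 (−0.53). Of the unfolded protein response genes, 11 fell and 0 rose when adjusted over the list alone, and 14 fell and 0 rose without inhibitor replicate 2. The unfolded protein response genes as a list had a median of −0.45, and −0.39 without inhibitor replicate 2 (camera, adjusted p = 0.00103, or adjusted p = 0.265 with an estimated correlation). Homologous recombination and Fanconi genes went both ways: FANCL (0.71), XRCC2 (0.65) and FANCI (0.71) rose while the acetyltransferase KAT5 (−0.57) and RAD54L (−0.39) fell, of 25 measured. For the homologous recombination and Fanconi genes the counts were 2 lower and 4 higher adjusted over the list alone, and 2 lower and 9 higher without inhibitor replicate 2. The homologous recombination and Fanconi genes as a list had a median of 0.23, and 0.12 without inhibitor replicate 2 (camera upward, adjusted p = 0.0120, or adjusted p = 0.419 with an estimated correlation). RAD54L was named after its value was seen. With length and GC trends removed 9 members were called higher and 0 lower, the calls of KAT5 (−0.37, adjusted p = 0.183) and RAD54L (−0.23, adjusted p = 0.119) being lost. Of the genes named in these lists, SRSF3, RBM39, TRA2B, SRSF7, SNRPF, SNRPG, RRP9, BYSL, NIP7, PES1, HSPA5, CALR, EDEM1, DNAJB11, FANCL, XRCC2, FANCI, KAT5 and RAD54L lost their calls without at least 1 library (highest adjusted p of each, 0.0643 to 0.180). Each was called in only 1 to 3 of the 6 fits that left out 1 library.

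Some mitochondrially encoded transcripts were higher. MT-CO3 went from 2682 ± 72.2 to 5984 ± 875 FPKM (SD, n = 3 each; log2 fold change 1.15, adjusted p = 0.0111), and MT-CYB (1.24), MT-ATP6 (0.97) and MT-ND3 (0.70) rose too, making 4 of 13 genes measured. Adjusted over the list alone, 0 of the mitochondrially encoded genes fell and 4 rose; without inhibitor replicate 2 it was 0 and 8. The list median of 0.73 (camera, adjusted p = 0.00145; adjusted p = 0.419 with an estimated correlation) became 0.34 without inhibitor replicate 2, the library with the mitochondrial share of 11.3%, and the call was lost with quantile normalization (adjusted p = 0.121) and without a filter on low values (adjusted p = 0.107). Among the 25 nuclear oxidative phosphorylation genes NDUFB5 rose (0.53) and none fell; their median was −0.11 although the test pointed upward (adjusted p = 0.676). Of the nuclear oxidative phosphorylation genes, 0 fell and 0 rose when adjusted over the list alone, and 2 fell and 7 rose without inhibitor replicate 2. That list was called without inhibitor replicate 2 (median 0.14, adjusted p = 0.0383, but adjusted p = 0.377 with an estimated correlation). Glycolysis and hypoxia genes went both ways, 6 higher and 2 lower of 24: PFKFB4 (0.96), BNIP3 (0.76) and EGLN3 (0.82) rose, while the peptide hormone gene ADM went from 159.9 to 47.3 FPKM (−1.83) and PFKFB3 (−0.83) fell. For the glycolysis and hypoxia genes the counts were 2 lower and 8 higher adjusted over the list alone, and 2 lower and 11 higher without inhibitor replicate 2. That list, with a median of 0.14, was not called (adjusted p = 0.0610). It was called without inhibitor replicate 2 (median 0.21, adjusted p = 0.0123, but adjusted p = 0.274 with an estimated correlation), without DMSO replicate 3 (adjusted p = 0.0460), with quantile normalization (adjusted p = 0.0157) and with trends removed (adjusted p = 0.0428). Cholesterol synthesis genes TM7SF2 (0.80), HSD17B7 (0.43), INSIG1 (0.47) and SQLE (0.60) rose and none of the 25 fell. Without inhibitor replicate 2, 1 of the cholesterol synthesis genes fell and 8 rose, and adjusted over the list alone 0 fell and 4 rose. The cholesterol synthesis genes as a list had a median of 0.10, and 0.20 without inhibitor replicate 2 (camera, adjusted p = 0.0925, or adjusted p = 0.375 with an estimated correlation). That list was called without inhibitor replicate 2 (adjusted p = 0.0223, but adjusted p = 0.272 with an estimated correlation), with the filter at 5 FPKM (adjusted p = 0.0339), with quantile normalization (adjusted p = 0.0152) and with trends removed (adjusted p = 0.0428). Among 18 PRMT5 cofactors and methionine cycle genes, methionine synthase MTR rose (0.90), and ornithine decarboxylase ODC1 (−0.87), ADI1 (−0.53), ENOPH1 (−0.44), WDR77 and the polyamine acetyltransferase SAT1 (−1.89) fell. Of the cofactor and methionine cycle genes, 7 fell and 1 rose when adjusted over the list alone, and 9 fell and 1 rose without inhibitor replicate 2. The cofactor and methionine cycle genes as a list had a median of −0.31, and −0.23 without inhibitor replicate 2 (camera, adjusted p = 0.0610, or adjusted p = 0.375 with an estimated correlation). That list was called without a filter on low values (adjusted p = 0.00215). MTAP, which salvages methionine, stood at 2.42 ± 0.208 FPKM in DMSO and 2.67 ± 0.313 FPKM with the inhibitor (log2 fold change 0.10, adjusted p = 0.598; below 0 when length and GC trends were removed). PFKFB3 and SAT1 were named after their values were seen. Of the metabolic genes named, MT-CO3, MT-CYB, MT-ATP6, MT-ND3, NDUFB5, PFKFB4, BNIP3, EGLN3, ADM, PFKFB3, TM7SF2, HSD17B7, INSIG1, SQLE, MTR, ODC1, ADI1, ENOPH1 and SAT1 lost their calls without at least 1 library (highest adjusted p of each, 0.0556 to 0.158). Each was called in only 1 to 4 of the 6 fits that left out 1 library.

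Genes regulated by p53 moved in both directions. DDB2 (17.4 to 35.6 FPKM, 0.99), XPC (0.82), FDXR (0.85) and POLH (0.59), which act in DNA repair, translesion synthesis or redox metabolism, rose, and GDF15, the death receptors FAS (−0.88) and TNFRSF10B (−0.78), PLK3 (−1.40) and AEN (−1.09) fell, of 21 measured. For the p53 targets the counts were 6 lower and 8 higher adjusted over the list alone, and 6 lower and 8 higher without inhibitor replicate 2. The p53 targets as a list had a median of 0.18, and 0.11 without inhibitor replicate 2 (camera, adjusted p = 0.474, or adjusted p = 0.816 with an estimated correlation). CDKN2A, which encodes p16INK4A and p14ARF, stood at 107 ± 11.2 FPKM in DMSO and 50.1 ± 22.1 FPKM with the inhibitor and was not called (log2 fold change −1.19, adjusted p = 0.0693), although it was without inhibitor replicate 2 (−0.76) and with length and GC trends removed (−1.01, adjusted p = 0.0237). In the integrated stress response list the amino acid transporter SLC7A5 (0.79), PSPH (0.68), ALDH1L2 (0.68) and PSAT1 (0.46) rose, and the transcription factors ATF3 (−1.22) and CEBPB (−1.28) and TRIB3 (−0.72) fell, of 22. Adjusted over the list alone, 5 of the integrated stress response genes fell and 4 rose; without inhibitor replicate 2 it was 7 and 6. The integrated stress response genes as a list had a median of −0.14, and −0.08 without inhibitor replicate 2 (camera, adjusted p = 0.558, or adjusted p = 0.917 with an estimated correlation). In the cell cycle lists RRM2 (0.77) and PRIM1 (3.65 to 8.51 FPKM) rose among 44 G1/S genes, and TOP2A rose (0.66) while CKS2 (−1.33), RANGAP1 (−0.71) and HJURP (−0.38) fell among 53 G2/M genes. Of the G1/S genes, 0 fell and 2 rose when adjusted over the list alone, and 5 fell and 8 rose without inhibitor replicate 2. The G1/S genes as a list had a median of 0.11, and 0.05 without inhibitor replicate 2 (camera, adjusted p = 0.146, or adjusted p = 0.375 with an estimated correlation). For the G2/M genes the counts were 1 lower and 0 higher adjusted over the list alone, and 13 lower and 9 higher without inhibitor replicate 2. The G2/M genes as a list had a median of 0.02, and −0.11 without inhibitor replicate 2 (camera, adjusted p = 0.877, or adjusted p = 0.943 with an estimated correlation). The G1/S list was called with the filter at 5 FPKM (adjusted p = 0.0200), with quantile normalization (adjusted p = 0.0174) and with trends removed (adjusted p = 0.0428), but not with an estimated correlation (adjusted p = 0.375). Among 11 interferon response genes IRF7 (29.6 to 101 FPKM, 1.68) and IFIT1 (0.73) rose and ISG15 fell (−1.59). Without inhibitor replicate 2, 3 of the interferon response genes fell and 4 rose, and adjusted over the list alone 3 fell and 3 rose. The interferon response genes as a list had a median of −0.04, and −0.06 without inhibitor replicate 2 (camera, adjusted p = 0.879, or adjusted p = 0.943 with an estimated correlation). Of 11 MHC class I genes the peptide transporter TAP1 fell (−0.80), and of 5 Wnt targets the Wnt antagonist DKK1 (−1.23). Of the MHC class I genes, 3 fell and 0 rose when adjusted over the list alone, and 3 fell and 2 rose without inhibitor replicate 2. The MHC class I genes as a list had a median of −0.38, and 0.00 without inhibitor replicate 2 (camera, adjusted p = 0.350, or adjusted p = 0.845 with an estimated correlation). For the Wnt targets the counts were 1 lower and 0 higher adjusted over the list alone, and 1 lower and 2 higher without inhibitor replicate 2. The Wnt targets as a list had a median of 0.05, and 0.01 without inhibitor replicate 2 (camera, adjusted p = 0.877, or adjusted p = 0.943 with an estimated correlation). Median, mean and test differed in sign for the p53, G2/M, interferon and Wnt lists. FDXR, POLH, PLK3, AEN, TNFRSF10B, ALDH1L2, PSAT1 and TRIB3 were named after their values were seen. Of the genes named here, FDXR, POLH, PLK3, AEN, TNFRSF10B, SLC7A5, PSPH, ALDH1L2, PSAT1, ATF3, CEBPB, TRIB3, RRM2, PRIM1, TOP2A, CKS2, RANGAP1, HJURP, IRF7, IFIT1, ISG15 and TAP1 lost their calls without at least 1 library (highest adjusted p of each, 0.0529 to 0.176), and HJURP also with trends removed (adjusted p = 0.0501). Each was called in only 1 to 4 of the 6 fits that left out 1 library.

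The membrane mucin MUC1 rose from 21.8 ± 1.801 to 48.3 ± 1.196 FPKM (SD, n = 3 each; 1.11) and the claudin CLDN4 fell (−0.78) among 10 of 20 epithelial genes that passed the filter. Adjusted over the list alone, 1 of the epithelial genes fell and 2 rose; without inhibitor replicate 2 it was 2 and 5. The epithelial genes as a list had a median of 0.33, and 0.30 without inhibitor replicate 2 (camera, adjusted p = 0.143, or adjusted p = 0.375 with an estimated correlation). They were called as a list without inhibitor replicate 2 (adjusted p = 0.0389, but adjusted p = 0.520 with an estimated correlation) and with the filter at 5 FPKM (adjusted p = 0.0136). The hyaluronan receptor CD44 (47.5 to 20.2 FPKM, −1.20), TGFBI (−1.12) and TGFB1 (−0.57) fell and none rose among 13 of 18 mesenchymal genes that passed the filter. Of the mesenchymal genes, 4 fell and 0 rose when adjusted over the list alone, and 7 fell and 0 rose without inhibitor replicate 2. The mesenchymal genes as a list had a median of −0.34, and −0.27 without inhibitor replicate 2 (camera, adjusted p = 0.0358, or adjusted p = 0.265 with an estimated correlation). That call was lost without inhibitor replicate 1 (adjusted p = 0.0872), with quantile normalization (adjusted p = 0.0599) and with the filter at 5 FPKM (adjusted p = 0.158). Of 26 genes of the classical pancreatic cancer programme 2 were measured, and the mucin MUC13 fell from 51.3 to 18.9 FPKM (−1.40). For the classical programme genes the counts were 2 lower and 0 higher adjusted over the list alone, and 2 lower and 0 higher without inhibitor replicate 2. The classical programme genes as a list had a median of −0.89, and −0.94 without inhibitor replicate 2 (camera, adjusted p = 0.0340, or adjusted p = 0.315 with an estimated correlation). Its call was lost without inhibitor replicate 1 (adjusted p = 0.0594) or 3 (adjusted p = 0.0629), without a filter (adjusted p = 0.238), with the filter at 5 FPKM (adjusted p = 0.0741) and with trends removed (adjusted p = 0.0900). In the basal-like programme, called as a list only without a filter (adjusted p = 0.0270; adjusted p = 0.772 for all libraries with an estimated correlation), KRT7 (−0.66), FAM83A (−0.73), KRT15 (−0.73) and AREG (−1.28) fell, and LY6D (0.69) and TNS4 (0.39), named after their values were seen, rose among 11. Without inhibitor replicate 2, 5 of the basal-like programme genes fell and 3 rose, and adjusted over the list alone 5 fell and 2 rose. The basal-like programme genes as a list had a median of −0.54, and −0.35 without inhibitor replicate 2 (camera, adjusted p = 0.148, or adjusted p = 0.772 with an estimated correlation). Of these genes, CLDN4, KRT7, FAM83A, KRT15, AREG, LY6D, TNS4 and TGFB1 lost their calls without at least 1 library (highest adjusted p of each, 0.0591 to 0.186). Each was called in only 1 to 3 of the 6 fits that left out 1 library. With trends removed the calls of KRT7 (−0.46, adjusted p = 0.0627) and TGFB1 (−0.35, adjusted p = 0.0635) were lost.

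Markers of other cell types were nearly absent from the genes measured. None of 13 acinar and islet markers and none of 12 leukocyte markers passed the filter. Of 10 fibroblast markers 2 did: the receptor PDGFRB rose from 1.03 ± 0.166 to 4.65 ± 0.512 FPKM (SD, n = 3 each; 1.47), and the list was not called with the filter at 5 FPKM (adjusted p = 0.178). Of the fibroblast markers, 0 fell and 2 rose when adjusted over the list alone, and 0 fell and 2 rose without inhibitor replicate 2. The fibroblast markers as a list had a median of 1.11, and 1.22 without inhibitor replicate 2 (camera, adjusted p = 0.0216, or adjusted p = 0.265 with an estimated correlation). Of 8 endothelial markers CDH5 alone was measured and fell (−0.76); its call was lost without any 1 of 5 libraries, inhibitor replicate 2 being the exception (highest adjusted p = 0.121), and with trends removed (adjusted p = 0.0613). For the endothelial markers the counts were 1 lower and 0 higher adjusted over the list alone, and 1 lower and 0 higher without inhibitor replicate 2. The endothelial markers as a list had a median of −0.76, and −0.90 without inhibitor replicate 2 (camera, adjusted p = 0.243, or adjusted p = 0.419 with an estimated correlation). Among the 30 ribosomal protein genes none was called; RPL8 stood at 712 ± 61.4 and 567 ± 206 FPKM and RPS2 at 987 ± 66.9 and 1137 ± 259.9 FPKM in DMSO and inhibitor libraries. Adjusted over the list alone, 0 of the ribosomal protein genes fell and 0 rose; without inhibitor replicate 2 it was 0 and 11. RPS2 was called higher without inhibitor replicate 2 (0.39) and with trends removed (0.40). The ribosomal protein list was called, upward, without inhibitor replicate 2 (adjusted p = 0.000393, but adjusted p = 0.489 with an estimated correlation) and not with all libraries (adjusted p = 0.925), so that result depended on 1 library, and the list median was −0.12 with it and 0.17 without. None of 11 nuclear-retained and other noncoding RNAs was called; MALAT1 stood at 87.7 ± 8.23 and 99.9 ± 15.2 FPKM and NEAT1 at 89.4 ± 2.21 and 144 ± 63.5 FPKM. Of the nuclear-retained and noncoding RNAs, 0 fell and 0 rose when adjusted over the list alone, and 5 fell and 2 rose without inhibitor replicate 2. The nuclear-retained and noncoding RNAs as a list had a median of −0.72, and −0.19 without inhibitor replicate 2 (camera, adjusted p = 0.447, or adjusted p = 0.845 with an estimated correlation). NEAT1 was called higher without inhibitor replicate 2 (1.01, adjusted p = 0.000246).

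Over all lists, 12 of the 31 with measured members were called with the preset correlation of camera, and none with an estimated correlation. Other splits of the 6 libraries into 3 against 3 gave up to 10 called lists.

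**Figure D4:**
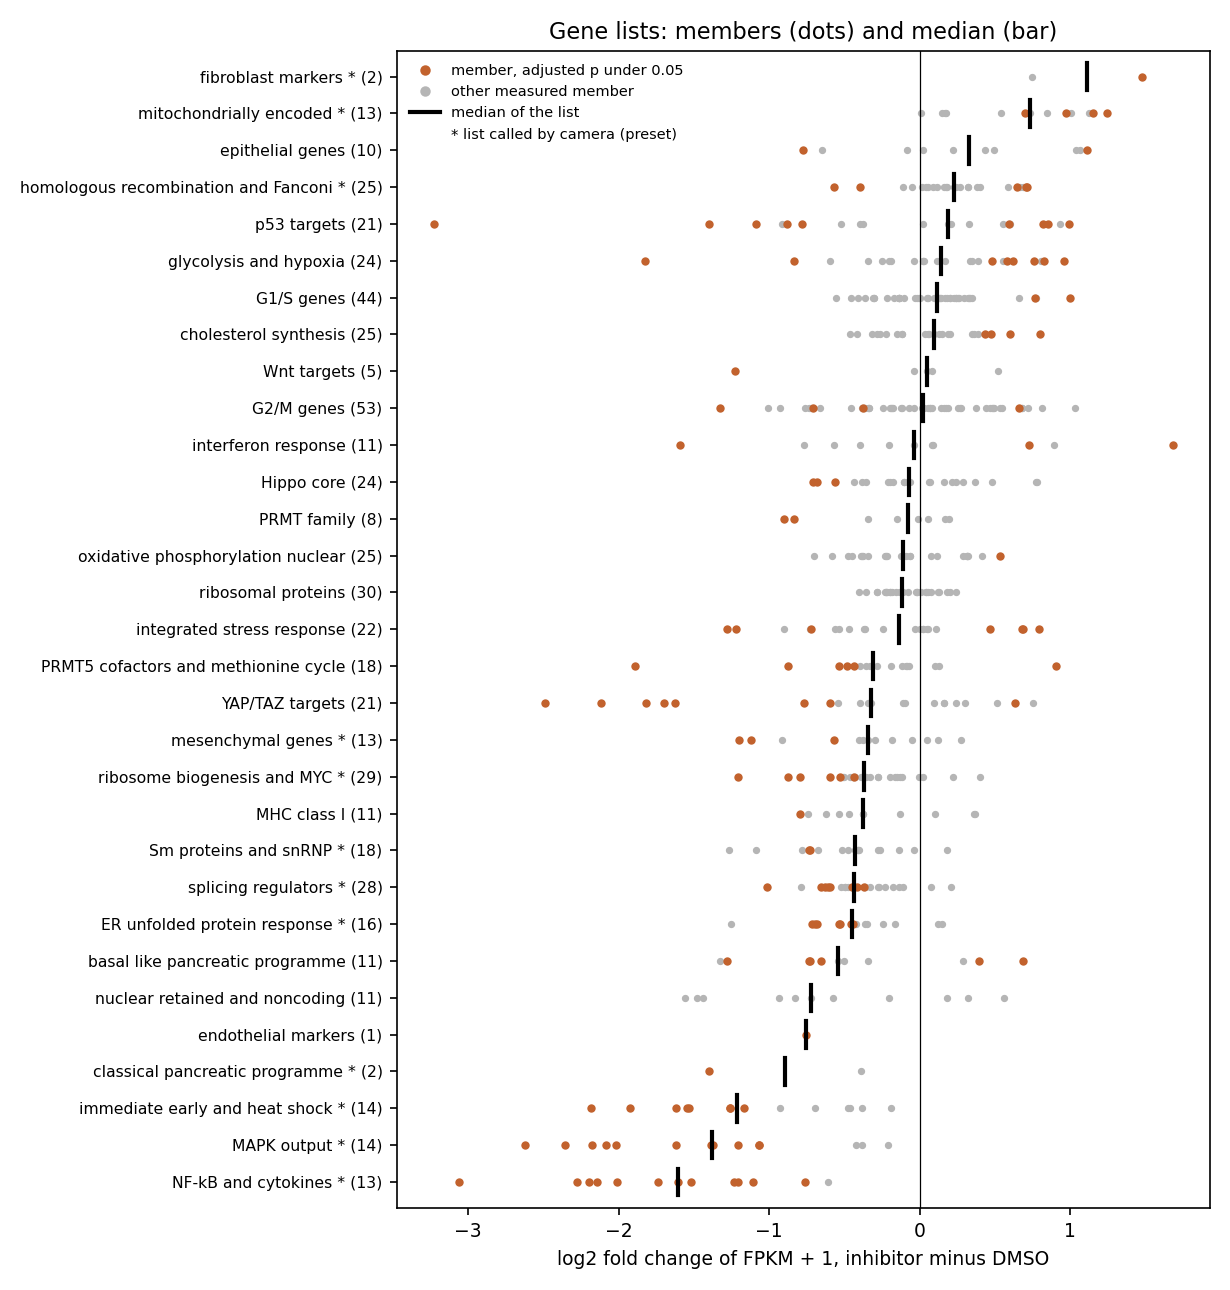
Log2 fold changes (inhibitor minus DMSO, FPKM + 1) of the measured members of each gene list, with the number measured in brackets; orange dots are called genes, grey dots the other members, and the black bar is the list median. Most members of the NF-κB, MAPK and immediate early lists lie to the left of 0, with medians of −1.61, −1.38 and −1.21, whereas the YAP and TAZ targets run from CCN1 at −2.49 to members above 0.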

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

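Library weights, voom and the joint removal of inhibitor replicate 2 and the trend were chosen after seeing the data; the other settings were fixed before. The 2339 called genes became 1533 without a filter on low values and 1505 with a filter at 5 FPKM, which test other numbers of genes (31192 and 7382). They became 4061 with length and GC trends removed, 7697 with library weights, and 6724 with inhibitor replicate 2 left out and the trend removed. The cause was not tested. Inhibitor replicates 1, 2 and 3 had library weights of 4.79, 0.0624 and 0.863. Results with library weights, that of the YAP and TAZ list below included, thus rest largely on inhibitor replicate 1 within its group. Stricter thresholds left 543 (adjusted p under 0.01) and 687 (at least 1 on the log2 scale). Under the 6 changes of pseudocount, scaling or rescaling and the 2 changes of prior the count ran from 2090 (quantile normalization) to 2338, and voom on recovered reads gave 2554. A fit of the 10564 protein-coding genes alone called 2330, whereas the main fit called 1864 of the same genes. The planned count tests were not run, because the deposited unit is FPKM; voom took their place. Leaving out 1 library in turn gave 478 to 5513 called genes, 46 to 113 of the 122 named genes (109 with all libraries) and 10 to 18 lists (12 with all).

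The YAP and TAZ target list kept a negative median in every setting, and passed the test without a filter (median −0.22, adjusted p = 0.00720), with library weights (−0.41, adjusted p = 0.0298) and by fry (−0.32, adjusted p = 0.00144), which does not compare it with other genes; without 1 library its median ran from −0.35 to −0.14, and it passed without inhibitor replicate 2. With trends removed the median was −0.11, the smallest of any setting (adjusted p = 0.0831). The cause was not tested. The count of called lists went from 12 to 0 with an estimated correlation and to 14 with fry. Sign changes, all of values not called, were STK4 (0.0451) and YAP1 (0.0675) with quantile normalization and MTAP (−0.0826) with trends removed, where STK3 became a called fall (−0.280, adjusted p = 0.0489). Leaving out 1 library moved STK3 from −0.295 to 0.0130 and LATS1 from −0.262 to 0.0384, above 0 without inhibitor replicate 3, LATS1 also without inhibitor replicate 1 (0.0135). Of the values of single genes under an alternative, 2392 kept direction and side of the threshold, 447 lost the call, 25 gained one and 6 changed sign.

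Labels share replicate numbers between groups. Deviations of same-numbered libraries from their group means correlated across genes at −0.018 (1), 0.157 (2) and 0.248 (3), so the numbers are not taken to pair the libraries; inhibitor replicate 1 correlated best with DMSO replicate 3, and replicates 2 and 3 with their own number. With a replicate block 1478 genes, 87 named genes and 10 lists were called, the classical and mesenchymal lists being lost, and the YAP and TAZ list had adjusted p = 0.122. The shallowest library held 14087260 reads, and no setting varied depth, so its limit was not measured. In the simulation the deviation of inhibitor replicate 2 lowered the recovery of 2-fold changes from 77.6% to 23.9%.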

Other observations

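In this part the tests of GC content and length and of listed zeros were set out before their results were seen; the tests of depth, a swap, replicate 2 alone, RNA interference, another cell line and other splits of the libraries, and the metallothionein list itself, were chosen after.

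Some metal-handling genes fell. Besides MT2A, the metallothioneins MT1E (47.8 to 13.1 FPKM, −1.82 on the log2 scale, adjusted p = 0.00451) and MT1X (−1.37, adjusted p = 0.0104) fell, as did the transferrin receptor TFRC, which imports iron (97.8 ± 4.51 to 17.7 ± 2.1002 FPKM, SD, n = 3 each; −2.40, adjusted p = 0.000662), and the ferritin heavy chain FTH1, which stores it (1791 ± 93.4 to 623 ± 57.3 FPKM; −1.52, adjusted p = 0.00301). Thus TFRC, whose transcript iron regulatory proteins stabilise, and FTH1, whose translation they block, both went down. Of 10 measured metallothionein and iron genes, MT4 not counted, 5 fell and none rose, while SLC30A1 (−0.03), SLC11A2 (0.13), STEAP3 (0.39), FTL (−0.44) and HMOX1 (−0.54) were not called. As the genes were chosen after MT2A and MT4 had been seen, no list test is given. If inhibitor replicate 2 alone were the source, the falls would be lost without it, but 7 of 10 were then called lower, FTL and HMOX1 in addition. MT1X lost its call without at least 1 library (highest adjusted p = 0.0572) and was called in 4 of the 6 fits that left out 1 library. FOLR1, named after its value was seen, a folate receptor and among the most abundant transcripts in DMSO, also fell, from 2864 ± 262 to 646 ± 221 FPKM (−2.21, adjusted p = 0.00695).

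Inhibitor replicate 2 differed from replicates 1 and 3 by an SD over genes of 0.666 on the log2 scale. Its deviation ran with GC content (Spearman's rho −0.52 across genes) and length (0.28), though the difference between replicates 1 and 3 also ran with GC content (−0.40). A smooth trend on GC content and length took up 32.8% of the variance of the deviation of replicate 2. With the trend removed the SD was still 0.547, against 0.306 between replicates 1 and 3, which argues against that trend as the whole cause. Low depth is argued against by its reads, 0.992 times those of the shallowest other library, and a swap with a DMSO library by its correlation with the other inhibitor libraries, higher by 0.0370 than that with DMSO (range among DMSO libraries 0.00308). A difference in RNA quality or library preparation, as part of the cause, and a different state of the cells stay open, since the labels give no batch and no biological explanation was tested.

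The lower PRMT5 transcript level was not expected from an inhibitor of the enzyme's activity as such. Inhibitor replicate 2 alone is argued against by the log2 fold change without it, −0.90, and a GC and length trend by the value after its removal, −0.75. RNA interference, which the design text of the series mentions, cannot be told apart from a response of transcription to the inhibitor: PRMT5 ranked 739 of 13578 from the largest fall, and a partial knockdown could give such a rank too. That inhibition of PRMT5 may lower its own transcript is thus a hypothesis, which libraries from cells known to have received the inhibitor alone would test.

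The pattern of cell identity genes differs in part from that described for BxPC-3, which is known to have lost SMAD4 and CDKN2A by homozygous deletion and to grow as an epithelial line. The keratins KRT8, KRT18 and KRT7 go with an epithelial origin. Of the 20 genes of the fixed epithelial list 10 passed the filter, among them ELF3 (43.2 FPKM in DMSO), MUC1 (21.8), DSP (15.1) and CLDN7 (12.4). KRT19, CDH1 and EPCAM at or near 0 and the reads of SMAD4 and CDKN2A do not go with the description of BxPC-3. A failure of estimates across genes is argued against, since 0 of the 55 nuclear oxidative phosphorylation and ribosomal protein genes were listed at 0 in any library. These 55 genes cannot show whether reads of a single gene, such as KRT19, were lost in counting. The read counter and its use of strand are not given, so that stays open. SMAD4 and CDKN2A had at least 562 reads in every library, so a candidate explanation is that the libraries came from another line than the label says, or from one that was mixed up in culture. Reads of SMAD4 and CDKN2A and zeros for KRT19 were found in both groups, whereas for CDH1 (0.118 ± 0.0273 FPKM in DMSO and 0.446 ± 0.0629 with the inhibitor), KRT8 and KRT18, higher with the inhibitor, and for CDKN2A and KRT7, lower with it, the 3 libraries of one group all lay above those of the other. Over the libraries SMAD4 had 562 to 754 reads and CDKN2A 1430 to 7562, which a homozygous deletion of the whole gene forbids. For SMAD4 and CDKN2A the reads thus argue against BxPC-3 cells as described. Reads were recovered per gene, so a deletion of part of a gene, or reads from an overlapping antisense gene, cannot be told from these values. Which cells the contrast describes is open, and no other line was compared.

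The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05 (the smallest is 0.1). For called genes 1 of the 10, the real split, gave as many, 2339, and the highest of the others gave 0. Every other split puts DMSO and inhibitor libraries together in each group, so the difference between inhibitor and DMSO widens the spread within groups. The 0 there is thus not a measure of chance. For called lists 1 of the 10 gave as many, 12, and the highest of the others gave 10.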
